A study of Saccharolobus islandicus with 2 samples.

How the data were processed

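Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map DNA bound by SisPerR, a protein that the series describes as a repressor of the oxidative response, in Saccharolobus islandicus REY15A, a thermoacidophilic archaeon. The labels list 2 libraries, 1 immunoprecipitated with an anti-SisPerR antibody and 1 input of sheared chromatin that was not immunoprecipitated. Both carry the strain label REY15A, the genotype label wild type, and E233S in their titles. Per the labels' protocols, cells were grown at 75 °C and cross-linked with 1% formaldehyde for 15 min, and the chromatin was sonicated to fragments of about 200 to 1000 bp. CASAVA and Bowtie2 are named in the submitters' processing notes, without versions. The peak caller, its threshold, the annotation tool, the name of the genome build, any filter on the peaks and the way the input was used are not given in the sources used here.

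The deposited table holds 1 row per peak, with the start and end of the peak on 1 RefSeq chromosome, an annotation class, the nearest gene, its protein or RNA identifier, and a signed distance in bp to the start of that gene. It holds no read count, height, fold enrichment, score or p-value. The depth of the 2 libraries is therefore unknown, and no peak has an error of its own. A table of the input library was not analysed here. With 1 library per group there is no replicate, so no test compares the immunoprecipitated library with the input or measures the spread between libraries. Every p-value below is over the peaks of this 1 list, and intervals cover counting error only. Coordinates are as deposited, and the table does not say whether starts count from 0 or 1. A distance of 0 was read as a peak that covers the start of its nearest gene. The sign convention of the other distances is not stated, so they are called positive and negative.

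The planned random placement of peaks against genes and the search for sequence words were not run, because both need the genome and gene coordinates of this strain, which were not used here. Gene names came from a RefSeq gene table of another strain, S. islandicus M.16.4 (assembly ASM2244v1), which was used for names and for which genes stand side by side, never for coordinates. A nearest gene was matched where its protein accession, which stands for 1 exact protein sequence, occurred in that table. Of 277 protein-coding nearest genes 65 matched, each to a single gene, and 13 of these carried a symbol. None of the locus tags occurred in that table. The 15 gene lists, fixed before the data were examined as search terms for product names, could only be applied to symbols, since neither table holds products. A gene counted as having a peak where it was the nearest gene of a peak, at any distance. The planned promoter windows would have needed gene coordinates. The lists were tested with Fisher's exact test, two-sided, among the 364 genes with a symbol in M.16.4, with Benjamini-Hochberg adjustment over the 15 lists. A gene whose protein differs between the strains cannot match, so this background is wider than the genes that could have been named.

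The naming rule, fixed before the data were examined, was to name the genes at the 20 strongest peaks and up to 10 members of the oxidative stress, metal and iron-sulfur lists and 4 of every other list, and any gene called PerR. Without a strength in the table, the first 20 rows were named in place of the 20 strongest, which was decided after the table was seen, and so was the naming of all 13 genes with a symbol and of their immediate neighbours in M.16.4. Row order followed the number in each peak's name (Spearman rho = 0.9998 across peaks, which are not independent replicates). What that order stands for is not stated, so it is reported as order only, and the planned test of peak strength by position was run on row order in its place. No gene is called PerR in either table, so the perR gene itself was not analysed here.

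The random placements are called permutation tests by random placement. Shares have exact (Clopper-Pearson) 95% binomial intervals. Row order was compared between peak classes with a permutation test of the difference in medians (100000 resamples, two-sided). The spacing of peak middles was compared with 10000 random placements of as many points between the first and the last peak, in bins of 50 kb. The p-values of these 2 kinds of test and of the numbering test, 5 in all, were adjusted together by Benjamini-Hochberg. The scans of the closing section were tested on simulated lists of 281 peaks. With no region thinned, the scan for a sparse window called 6 of 100 lists at the 0.05 threshold, and with 1 window thinned to 0.25 of its peaks it called 98 of 100. The scan of first-listed peaks called 1 of 100 random orders. The unthinned lists and the random orders came from the same models as the tests, so their rates say nothing of other layouts of peaks. The thinning was stronger than in the data, where the sparsest window held 0.391 times the median of windows that do not overlap it. The 98 of 100 is therefore not the rate of detection at the observed size. Alternatives were the first 140 rows alone, wider distances to a gene start, other bins and windows, random placements that kept the smallest observed spacing, and the addition of neighbouring genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.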

Results

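The deposited list held 281 SisPerR peaks on the chromosome of S. islandicus REY15A, from 1 immunoprecipitated library. All were 1098 bp wide with both ends counted, and together they covered 12.2% of the 2.52 Mb between the first and the last peak (positions 550 to 2520417). Every peak carried the same annotation class, a promoter within 1 kb, and each had a nearest gene of its own, 281 in all. The nearest gene was protein-coding at 277 peaks and an RNA gene at 4. Numbers in the peak names ran to 403, and 122 of them had no row. Rows were present for 156 of the numbers up to 201 (77.6%) and for 125 of the 202 later ones (61.9%), a difference past the threshold (Fisher's exact test, two-sided, p = 0.000746, adjusted p = 0.00373 over 5 tests). Neither library had a replicate, and the depth of both was unknown.

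The series asked which genes SisPerR binds. The list names only the nearest gene of each peak. Gene numbers were a mean of 926 bp apart, less than the peak width of 1098 bp, so a peak may also cover the starts of other genes. Such starts were not counted, because gene coordinates were not used. A covered start therefore does not single out the named gene as the one bound. The first row was the peak at upsF (SIRE_RS09570, positions 1737720 to 1738817), which covered the start of the gene. UpsF is a membrane protein of the Ups pilus, the UV-inducible type IV pilus through which Saccharolobus cells aggregate and exchange DNA. In the related strain M.16.4, upsF stands beside upsA, which encodes a pilin subunit of the same pilus. A second peak within the first 20 rows lay close by, covering the start of SIRE_RS09560 (positions 1734460 to 1735557). The other gene with a symbol in the first 20 rows was cimA (SIRE_RS09535, row 15, positions 1727781 to 1728878), which encodes citramalate synthase, an enzyme of isoleucine synthesis. Its peak lay at a distance of −112 bp from the gene start.

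Among the first 20 rows, 17 peaks covered the start of their nearest gene and 3 did not. Rows 2 to 8 had no name beyond a locus tag and were, in order, SIRE_RS05490 (from position 1038255), SIRE_RS04675 (884399), SIRE_RS04980 (947189), SIRE_RS02290 (409223), SIRE_RS06370 (1200137), SIRE_RS01395 (243804) and SIRE_RS02545 (459982). The SIRE_RS04675 peak was 348 bp from the start and the others covered it. Row 9 was SIRE_RS02335 (418348) and row 10 the RNA gene SIRE_RS07445 (1370294). SIRE_RS10140 (1835456), SIRE_RS08790 (1600974), SIRE_RS05145 (971787), SIRE_RS13575 (2512388) and SIRE_RS02810 (517583) followed, each with its start covered. SIRE_RS09610 (1746207) was row 20, at a distance of 84 bp. SIRE_RS08600 (row 14, 1571940 to 1573037) stands between aroC and aroB in M.16.4, which encode enzymes of the shikimate pathway to aromatic amino acids. SIRE_RS08405 (row 17, 1533836 to 1534933) stands beside ftsY, the receptor of the signal recognition particle.

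Genes of DNA replication and repair were among those with a peak. The list fixed for them matched mcm, the replicative helicase (SIRE_RS06220, row 237, positions 1176122 to 1177219, start covered), and nurA, a nuclease that resects DNA ends together with the HerA helicase (SIRE_RS00300, row 26, positions 53386 to 54483, at −612 bp from the start). These were 2 of the 13 genes with a symbol, against 5 such genes among the 364 symbols of M.16.4. The excess did not pass the threshold after adjustment (Fisher's exact test, two-sided, p = 0.0111, adjusted p = 0.167 over 15 lists). The count rests on taking nearest genes at any distance. The nurA peak had the most negative distance in the list and was among the 10 of 281 peaks further than 500 bp from a gene start. Under a limit of 500 bp only mcm would have counted for this list, and no test with such a limit was run. A gene could count as having a peak only if its protein was identical in both strains. The 364 symbols were not limited to such genes, so the test does not separate having a peak from having an identical protein. This list was the only one with p under 0.05 before adjustment, and the only one whose terms matched a symbol at a peak. Its terms include short gene names such as mcm and nurA, whereas many terms of the other lists are product names that symbols do not hold. The search terms missed pcn, the sliding clamp PCNA (SIRE_RS08085, row 111, positions 1478129 to 1479226), and ssb, the single-stranded DNA-binding protein (SIRE_RS00810, row 156, positions 143083 to 144180). Both peaks covered the gene start. They were picked by hand after their symbols were seen, and the 364 symbols were not picked over in the same way, so they add nothing to the test.

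The terms fixed for oxidative stress defence matched 0 symbols at a peak, and 1 symbol of M.16.4. They include thioredoxin, a small protein that reduces disulfides, but did not match the symbol of its gene, trxA. A peak covered the start of trxA (SIRE_RS00240, row 60, positions 42127 to 43224). This gene was noticed after its symbol was seen and was not counted in the test. The iron-sulfur list also had 0 members at a peak. SIRE_RS05880 (row 91, positions 1117356 to 1118453), whose start was covered, stands in M.16.4 beside sufC, the ATPase of iron-sulfur cluster assembly. Of the other 14 lists, 8 matched no symbol of M.16.4 at all, so nothing was measured for them. Among these were the metal transport, transcription regulator and respiratory chain lists. The ribosome and tRNA list and the cell surface and pili list were also among them, although rpsJ, rpmC, aspS and upsF were each nearest to a peak. The oxidative stress list matched 1 symbol, the iron-sulfur list 2, CRISPR-Cas 18, chromatin proteins 4, toxin-antitoxin 2 and chaperones 1, none of them at a matched peak. With 268 of 281 peaks lacking a symbol, these counts do not show that such genes lacked a peak.

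The remaining named genes belong to translation, RNA processing and cofactor synthesis. Peaks covered the starts of rpsJ (SIRE_RS09040, row 169, positions 1645552 to 1646649) and rpmC (SIRE_RS06575, row 164, 1231496 to 1232593), which encode ribosomal proteins. In M.16.4 rpsJ stands beside tuf, the gene of the elongation factor that delivers aminoacyl-tRNA. The peak at aspS, aspartyl-tRNA synthetase (SIRE_RS09345, row 204, 1700508 to 1701605), was 60 bp from the start. A peak covered the start of rnz, the endonuclease RNase Z that trims tRNA ends (SIRE_RS05335, row 93, 1004438 to 1005535). Peaks also covered the starts of cobS (SIRE_RS10250, row 196, 1853347 to 1854444) and cobA (SIRE_RS11735, row 241, 2158817 to 2159914), genes named for cobalamin synthesis. Of the 13 named genes 10 had their start covered. The other RNA genes were SIRE_RS09905 (row 69, at −48 bp from the start), and SIRE_RS09090 (row 151) and SIRE_RS06755 (row 163), both with the start covered.

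**Figure D1:**
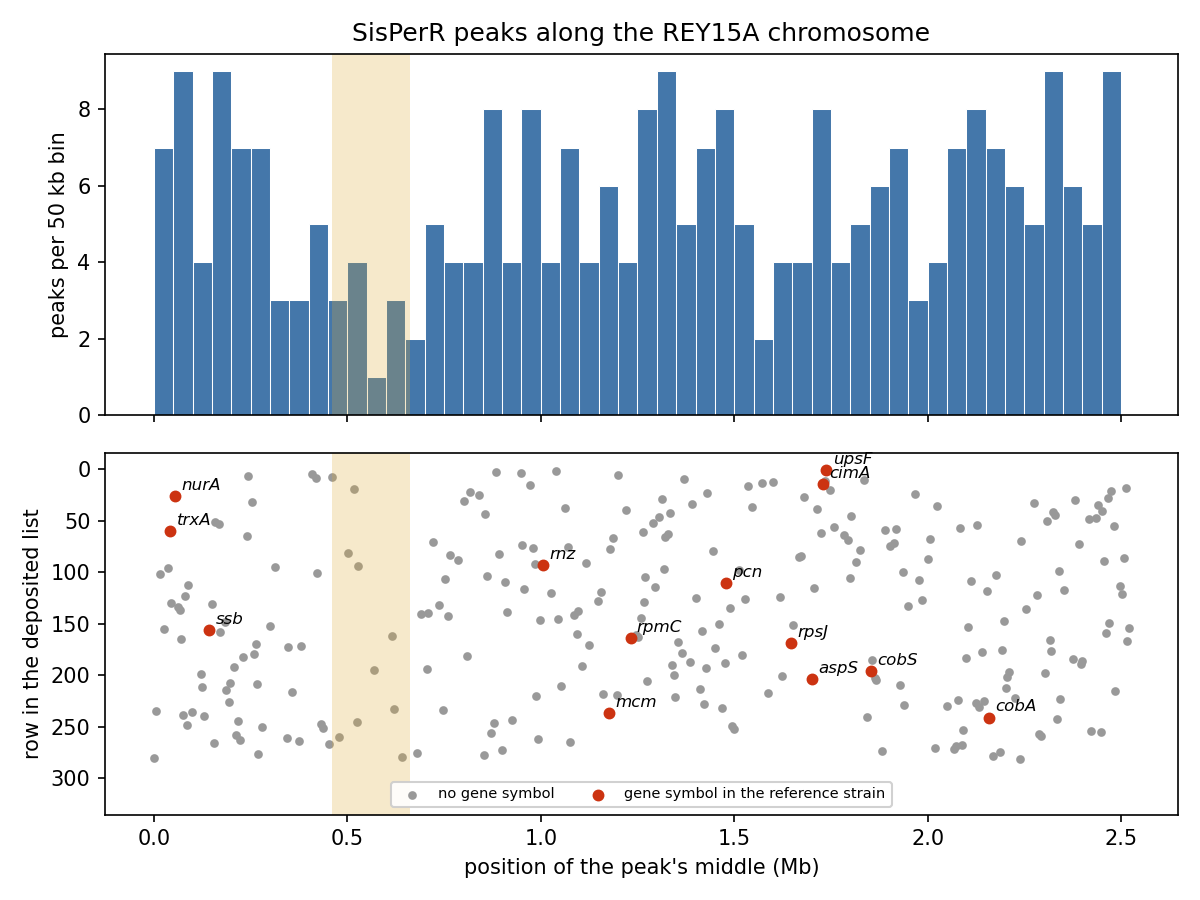
Top, the number of peaks in each whole 50 kb bin along the chromosome (Mb), which hold 276 of the 281 peaks. Bottom, each peak as a point at its position (Mb) and its row in the deposited list, with genes that have a symbol in red; upsF is row 1 and cimA row 15. The shaded band is the 200 kb window with the fewest peaks, 9.

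The second question was where peaks lay relative to genes. Of the 281 peaks, 214 covered the start of the nearest gene (76.2%, exact 95% interval 70.7 to 81.0%). Another 52 lay at a positive distance, with a median of 263 bp and a range of 4 to 955 bp, and 15 at a negative one, with a median of −103 bp and a range of −612 to −11 bp. Positive distances made up 77.6% of those 67 peaks (95% interval 65.8 to 86.9%). All but 10 peaks lay within 500 bp of a gene start. Every row carried the class of a promoter within 1 kb, so these shares do not show a preference for promoters. Random gene starts at the density of the locus tags were covered by a median of 72.1% of peaks (95% of simulations 66.8 to 77.2%). Peaks that covered a start stood earlier in the list, at a median row of 131.5 against 177 for the others (permutation test, two-sided, p = 0.0143, adjusted p = 0.0357 over 5 tests). The call was lost when peaks were ordered by the number in their name (permutation test, two-sided, p = 0.0206, adjusted p = 0.0516). In the first 140 rows 113 peaks covered a start (80.7%, 95% interval 73.2 to 86.9%), and in the other 141 rows 101 did (71.6%, 63.4 to 78.9%), which did not differ at the 0.05 threshold when the list was halved in this way (Fisher's exact test, two-sided, p = 0.0927).

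**Figure D2:**
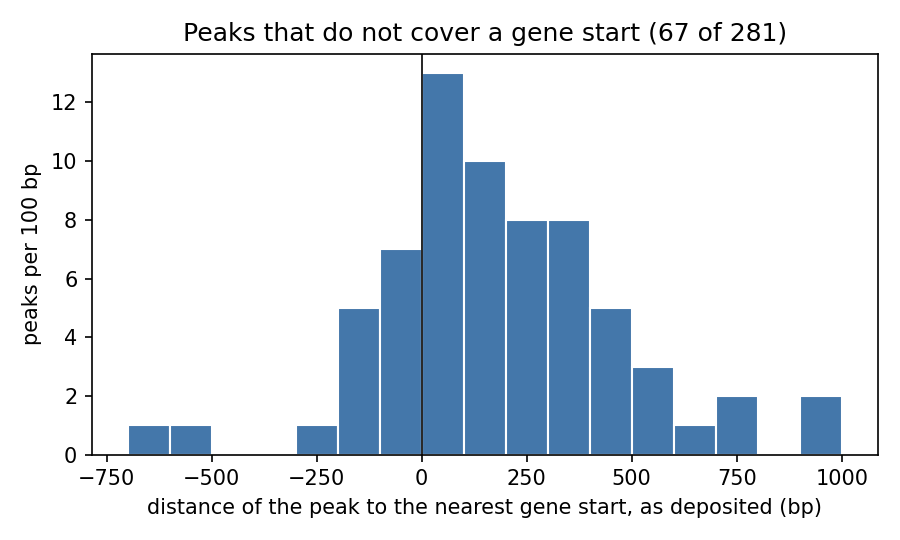
The number of peaks per 100 bp of distance (bp) for the 67 of 281 peaks that did not cover the start of their nearest gene, with the sign as deposited. Of these, 52 lie to the right of 0 and 15 to the left.

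Peaks were spread between positions 550 and 2520417. The median spacing between neighbouring peak middles was 6699 bp (quartiles 4621 and 11006 bp), against a median of 6202 bp in random placements, a difference that chance placement covered (permutation test by random placement, two-sided, p = 0.203, adjusted p = 0.339). The fullest of 50 bins of 50 kb held 9 peaks and the emptiest 1, and random placements gave a median of 11 and 1 (one-sided permutation tests by random placement, p = 0.9997 for as many or more and p = 0.721 for as few or fewer, adjusted p = 0.9997 and 0.901). The fullest bin was low rather than high for random placements (one-sided permutation p = 0.0349 for as few or fewer, unadjusted), but not for placements that kept the smallest observed spacing (p = 0.478). No spacing was below 2255 bp. The 3 widest spacings were between the peaks at SIRE_RS03020 and SIRE_RS03265 (46.5 kb), at SIRE_RS02845 and SIRE_RS03020 (41.1 kb), and at SIRE_RS03435 and SIRE_RS03605 (38.4 kb). All 3 fell between positions 527319 and 678638.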

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

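All alternatives reported here were chosen after the table was seen, except the bins of 20 kb. Counting peaks within 100, 200 or 500 bp of a gene start along with those covering it raised the share at a start to 83.3%, 88.6% and 96.4%, as the wider definition must. By the number in the peak name, peaks that covered no start stood 60.5 numbers later at the median, on a scale that runs to 403 with gaps. By row they stood 45.5 of 281 rows later, so the differences are in unlike units and neither is shown to be larger. The adjusted permutation p rose from 0.0357 by row to 0.0516 by number, and the cause was not tested. In the first 140 rows the median distance of peaks that covered no start was 317 bp, against 186 bp in the whole list, and the cause was not tested. The median spacing lay above that of random placements in the main comparison and below it when these kept the smallest observed spacing (6699 bp observed, p = 0.470) or when the first 140 rows were used alone (11545 bp observed, p = 0.419; permutation tests by random placement). It passed the threshold in none of the 3, and the cause was not tested. In the first 140 rows the share covering a start was 80.7% and the share of positive distances 81.5%, against 76.2% and 77.6% in the whole list. These 2 shares were not tested against a threshold in the alternatives. The replication and repair list stayed short of the threshold in the alternatives run, with its adjusted p between 0.167 and 1 (Fisher's exact test). Neither the fullest nor the emptiest bin rose above its random median in any setting: the fullest 50 kb bin held 9 peaks against 11, against 10 with the smallest spacing kept and 7 against 7 in the first 140 rows, and the emptiest held 1 against 1 and against 2 with the smallest spacing kept. With 20 kb bins the fullest held 5 peaks, below the range of 95% of random placements without a minimum spacing (6 to 9, one-sided permutation p = 0.0241 for as few or fewer, unadjusted). These bins were not run with the smallest spacing kept, which at 50 kb raised the like permutation p from 0.0349 to 0.478. The 20 kb value therefore does not show that peaks were evenly spread. No alternative by fold enrichment or by p or q could be run, since the table holds neither, nor could promoter windows, the overlap of whole peaks with them, another peak point, a background of operon-leading genes, the authors' assignment as an alternative, since it is the only one here, or the window for sequence words. No paired analysis was possible because each group has 1 library. The unknown depth limits every absence: a gene with no peak cannot be told from one under the authors' threshold or among the 122 numbers with no row.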

Other observations

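Matched genes with no symbol that are not described above stand in M.16.4 beside the following named genes. SIRE_RS00265 (row 130, positions 44859 to 45956) stands beside clsN, which encodes coalescin, a chromosome-organising protein of the SMC type. SIRE_RS10415 (row 59) stands beside gapN, a glyceraldehyde-phosphate dehydrogenase, SIRE_RS06055 (row 128) beside ppsA, phosphoenolpyruvate synthase, and SIRE_RS13215 (row 255) beside gltA, citrate synthase. SIRE_RS09165 (row 85) stands beside glmM, phosphoglucosamine mutase. SIRE_RS09670 (row 56) stands beside map, methionine aminopeptidase, SIRE_RS05745 (row 160) beside dph5 of diphthamide synthesis, SIRE_RS07405 (row 178) beside glyA and SIRE_RS13600 (row 167) beside asd of amino acid metabolism. SIRE_RS00140 (row 155) stands beside cobT, named for cobalamin synthesis like cobS and cobA. SIRE_RS12905 (row 73) stands beside sepP and SIRE_RS00370 (row 137) beside meaB. The order of genes in REY15A was not used here, so these are neighbours in M.16.4 only.

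All tests in this part were chosen after the list was seen. What the sparse window should show against chance and gene number, and what the covered gene starts should show, was written down only after the values bearing on them had been seen. The emptiest 200 kb window, positions 461099 to 661098, held 9 peaks, at SIRE_RS02630, SIRE_RS02735, SIRE_RS02810, SIRE_RS02825, SIRE_RS02845, SIRE_RS03020, SIRE_RS03265, SIRE_RS03310 and SIRE_RS03435, against a median of 23 in the windows that do not overlap it. It was picked as the emptiest, and the emptiest window of random placements that kept the smallest observed spacing held a median of 15 (95% of placements 11 to 17). So few occurred in a share of 0.0039 of these, and 300 kb windows gave 0.0017 (17 peaks against 25), both under the 0.05 threshold. The scan was chosen after the list was seen, which these shares do not allow for, so chance is not excluded. The call was lost with 100 kb windows (3 against 5, p = 0.0543) and without a minimum spacing (9 against 13, p = 0.0703, permutation tests by random placement). The ratio to the random median was 0.60 and 0.69 there and 0.60 in the 200 kb windows. Placements without a minimum held at least 41 spacings under 2255 bp. The list holds 0 by definition, since 2255 bp is its smallest spacing, so this count is not a test of the placements without a minimum. Locus tags, whose numbers follow the chromosome in steps of 5 except for 1, ran at 0.891 times the median density of windows that do not overlap it. On the same measure peaks ran at 0.391 times, a ratio lowered by the choice of the emptiest window. Against the emptiest random window, an unlike measure, peaks ran at 0.60 times. The locus tags stayed above a bound of 0.75, but the bound was set after the values were seen, so it decides nothing. Their density, 0.977 per kb, lay within the range of the windows that do not overlap it (0.934 to 1.27 per kb). How far fewer genes account for the gap was not tested. Peaks in the window stood at a median row of 195 against 139.5 for the others (exact Mann-Whitney test, two-sided, p = 0.217), which leaves open whether they are listed later; repeated DNA where reads do not map uniquely, rows missing from the list, and a real difference in binding may each account for the gap and were not tested.

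Among the first 20 rows, 4, at cimA, SIRE_RS09560, upsF and SIRE_RS09610, fell within 19.5 kb (positions 1727781 to 1747304). A permutation test on random orders of the same peaks gave p = 0.0788 for as many first-listed peaks in some 50 kb window, so chance order remains a possible explanation. The value depended on the window, since 20 kb windows gave a permutation p = 0.0023, and on the number of rows, since the first 10 rows gave p = 0.851 and the first 40 gave p = 0.139. A window of 20 kb just holds the 19.5 kb found in this same list, which favours a low p. Whether SisPerR binds the region around upsF more strongly than others may be asked of a table with peak heights.

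Most peaks cover a gene start, but this may follow from gene density and peak width alone. The locus tags spanned by the list make 2722 gene numbers, or 1 per 926 bp, less than the width of a peak. Random gene starts at that density, kept to peaks with a start within 1 kb as in the list, were covered by a median of 72.1% of peaks (95% of simulations 66.8 to 77.2%), against 76.2% observed (two-sided permutation p = 0.118, with starts placed at random). Real gene starts are not placed at random, and their strands were not used. Since every row carries the promoter class and 122 of 403 numbers have no row, the list can neither show nor deny a preference of SisPerR for promoters.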
